A study of Arabidopsis thaliana with 4 samples.

How the data were processed

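Total RNA of 10-day-old seedlings, extracted with a plant RNA column kit and labelled with biotin per the labels' protocols, was hybridised to 4 Affymetrix arrays, 2 of 35S:miR396 and 2 of wild-type plants. The deposited table holds probe set intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 subtracts local background and combines the probe pairs of each probe set into 1 signal. Its version, its scaling target and its detection calls were not given in the sources used here, so no probe set was called present or absent. The deposited signals reach 17815.2, and 6 values were at or under 0. The trimmed means of the arrays, with 2% taken off at each end, were 237 for wild type 1b, 230 for wild type 2, 197 for 35S:miR396 1 and 256 for 35S:miR396 2. The arrays had therefore not been brought to a common level, although the design of the tests had assumed so. That design was kept, and quantile-normalized and median-centred values were set beside it. Scaling adds or removes a shift shared by all genes, and MAS5 signals near background are imprecise on the log scale.

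Of 22810 probe sets, 64 Affymetrix controls were left out. In the platform annotation used here, 13513 of the other 22746 probe sets had 1 gene, 503 had several and 8730 had none. Gene symbols were updated through RefSeq names of the TAIR10.1 assembly, which matched 13436 probe sets to 13286 loci, and no coordinates were taken from it. A probe set with several genes or none was left unnamed. Many well-known genes were thus not read here, and a list counts only members with a probe set of 1 gene. For a gene with several such probe sets the one with the highest mean level was taken.

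Groups came from the sample titles. Values at or under 0 were set to 0.1, the smallest positive value, and log2 was taken. The 30% of probe sets with the lowest mean log2 signal were left out, which kept 15923 with a mean signal of at least 15.8. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on mean level, two-sided), without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with 3 or more tested members were compared with all other tested probe sets by limma's camera with a preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry stood beside it. With an estimated correlation camera also takes its degrees of freedom from the arrays. Those are 2 without a block and 1 with one, so a list passes less easily. Other lists were described by their members, with the Benjamini-Hochberg adjustment over the list alone. The count of probe sets at least 2-fold apart in all 4 pairs of arrays was made without a test for the genotypes and for the other splits of the 4 arrays. Because 2 against 2 arrays have 3 splits, no permutation test can pass 0.05. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

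The tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes all measured members of the GRF lists and of the list of other miR396 targets, the 12 highest and 12 lowest single-gene probe sets by moderated t that separate the genotypes on all 4 arrays, and up to 4 members with the largest absolute moderated t from each list. Genes past the threshold come first, and places left are filled by the next genes by moderated t, named as not past it. Here all 24 places were filled in that second way. Probe sets counted in groups of 5 or fewer were named after their values were seen.

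Alternatives were quantile normalization, centring of each array on its median, no filter, a filter on the lowest 60%, a pseudocount of 2.4 (the 10th percentile of all values), eBayes without a trend and with robust fitting, other thresholds, each array left out in turn, and the replicate number as a block. Lists of further mitosis genes and of further DNA replication genes, and the combination of the block with another scaling, were added after the first results were seen. The scripts were tested on simulated data made from these arrays with 200 of 15923 probe sets changed. The comparison without a block recovered 15.5% of 2-fold changes, 92.0% of 4-fold changes and 98.5% of 8-fold changes, with 2, 9 and 13 false calls. With the replicate number as a block, 87.0%, 95.5% and 98.0% were recovered, with 8, 10 and 7 false calls. This simulation was made from quantile-normalized values and the one without a block from deposited values. The one without a block also held no difference between replicate numbers. The gain can therefore not be credited to the block alone. In both, probe sets varied independently, each with the spread that the trend gives for its mean level. None had a larger spread of its own, as some have on the arrays. The recovered shares may therefore not hold for the arrays. With the preset correlation, camera called 3% of simulated lists of 8 genes with no shift and 98% of those shifted by 0.5 on the log2 scale. The simulated genes varied independently, so the 3% does not give the error rate for lists whose genes vary together. On the deposited signals the estimated correlation was 0.36 for the G2/M list and 0.82 for the core histones. After quantile normalization it was 0.55 and 0.0017, so the histone value depends on the scaling of the arrays. Even there the camera p of the histones went from 0.0023 with the preset to 0.0904 with the estimated correlation.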

Results

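Transcript levels were measured on Affymetrix arrays in whole Arabidopsis thaliana seedlings of the ecotype Col-0, 10 days old, grown under long days at 23 °C. Each of 4 arrays held total RNA of seedlings of 1 genotype: 2 arrays of 35S:miR396 plants and 2 of wild type. In 35S:miR396 plants the microRNA miR396 is overexpressed, driven by the 35S promoter of cauliflower mosaic virus, which is active in most plant tissues. The labels number the wild-type arrays 1b and 2 and the 35S:miR396 arrays 1 and 2. They do not state whether the replicates came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical. The median signal of the 22746 probe sets left after removal of controls was 72.8 on wild type 1b, 71.3 on wild type 2, 60.5 on 35S:miR396 1 and 81.3 on 35S:miR396 2. The number of arrays limits the precision. In the comparison of the genotypes, which had no term for the replicate number, the median half-width of the 95% interval of a log2 fold change was 0.74.

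The comparison of 35S:miR396 with wild type asks which transcripts differ when miR396 is overexpressed. No single gene passed the test without a term for the replicate number, and the genes farthest apart by moderated t included a pair of defensins with a lower signal in 35S:miR396. PDF1.2, a plant defensin induced by jasmonate and ethylene, had a signal of 331 ± 104 (SD, n = 2) in wild type and 135 ± 46.0 (SD, n = 2) in 35S:miR396, a log2 fold change of -1.30 with a 95% interval from -2.08 to -0.53. Its close relative PDF1.2b stood at 642 ± 140 and 279 ± 104, a log2 fold change of -1.24. AT3G16670 was the highest by moderated t, at 214 ± 84.8 in wild type and 607 ± 197 in 35S:miR396, a log2 fold change of 1.52 with an interval from 0.73 to 2.32. Of 15923 probe sets tested with limma in this way, 0 passed an adjusted p of 0.05 and the lowest adjusted p was 1, while 85 lay under an unadjusted p of 0.05 (29 higher and 56 lower in 35S:miR396). Chance alone would put 796 there, so the 85 are no sign of differences. They are no sign of their absence either, as the error in this comparison includes the spread between the replicate numbers. With the number as a block, although the labels do not state that it pairs the arrays, 5 passed. With the block and quantile normalization the count was 0, and with the block and centring it was 3. Without the block, 3 passed with the lowest 60% of probe sets left out. AT3G02480 passed in this fit and among the 5, at 1184 and 1995 in wild type and 20.4 and 1410 in 35S:miR396. An unnamed probe set did so too, at 466 and 1492 against 39.3 and 705. LEA4-5, among the 5, was at 50.2 and 117 against 6.2 and 77.4. Each rests on 35S:miR396 1, as 35S:miR396 2 lay within the wild-type range. AT3G16670 and AT4G16260 separated the genotypes. In both fits limma took the error from the trend alone (infinite prior degrees of freedom), not from each probe set.

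The 12 genes named as higher in 35S:miR396 did not pass the threshold in this comparison, but their signals on both 35S:miR396 arrays exceeded those on both wild-type arrays. WRKY53, a transcription factor of leaf senescence and defence, was at 13.0 and 45.2 in wild type and at 74.5 and 66.8 in 35S:miR396. CML23, a calmodulin-like calcium sensor, stood at 29.2 and 92.5 against 98.7 and 174. AGL24, a MADS-box gene that promotes flowering, stood at 32.2 and 23.9 against 43.1 and 91.5. ATL63, of the ATL family of RING-finger ubiquitin ligases, was at 7.9 and 17.5 against 33.2 and 40.3, and AT1G12630, of the AP2/ERF transcription factor family, at 8.7 and 13.1 against 30.6 and 49.7. Both had low signals in wild type, against which a fold is imprecise. The remaining 6 were AT4G31330, AT5G19580, AT5G15780, AT3G42800, AT3G10930 and AT3G28960, and log2 fold changes over the 12 lay between 1.13 and 1.87. With 1 array left out, 7 of these 12 log2 fold changes shrank by over 1.5 times: WRKY53 to 0.64, CML23 to 0.50, AT3G10930 to 0.38 and ATL63 to 1.06 without wild type 1b, AT4G31330 to 1.05 and AT3G42800 to 0.68 without wild type 2, and AGL24 to 0.64 without 35S:miR396 2.

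The 12 genes named as lower in 35S:miR396 did not pass it either. AT4G16260, which belongs to the family of beta-1,3-glucanases, had the most negative moderated t, with signals of 57.8 and 105 in wild type and 33.6 and 16.5 in 35S:miR396 and a log2 fold change of -1.73. ATSMC2, a subunit of the condensin complex that compacts chromosomes, was at 51.4 ± 3.61 (SD, n = 2) in wild type and 19.2 ± 6.72 in 35S:miR396, a log2 fold change of -1.47. AT2G47880, of the glutaredoxin family, was at 266 ± 4.88 against 134 ± 7.99, a log2 fold change of -0.99. QQS, a gene linked to leaf starch content, was at 157 ± 12.6 against 85.4 ± 4.95, a log2 fold change of -0.88. AT3G17520, of the late embryogenesis abundant protein family, had a log2 fold change of -1.91, which was -0.90 without 35S:miR396 1, where its signal was 7.1. The others besides PDF1.2 and PDF1.2b were AT1G65920, AT3G16120, AT5G60150, AT4G22160 and AT1G33930, and the log2 fold change of AT4G22160 went from -1.34 to -0.67 without 35S:miR396 1. Signals that separate the genotypes on all 4 arrays were found for 2040 of the 15923 probe sets, or 12.8%, where random order of 2 against 2 arrays gives 33.3%. The 24 genes were picked for such separation, so it is not further evidence of a difference.

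**Figure D1:**
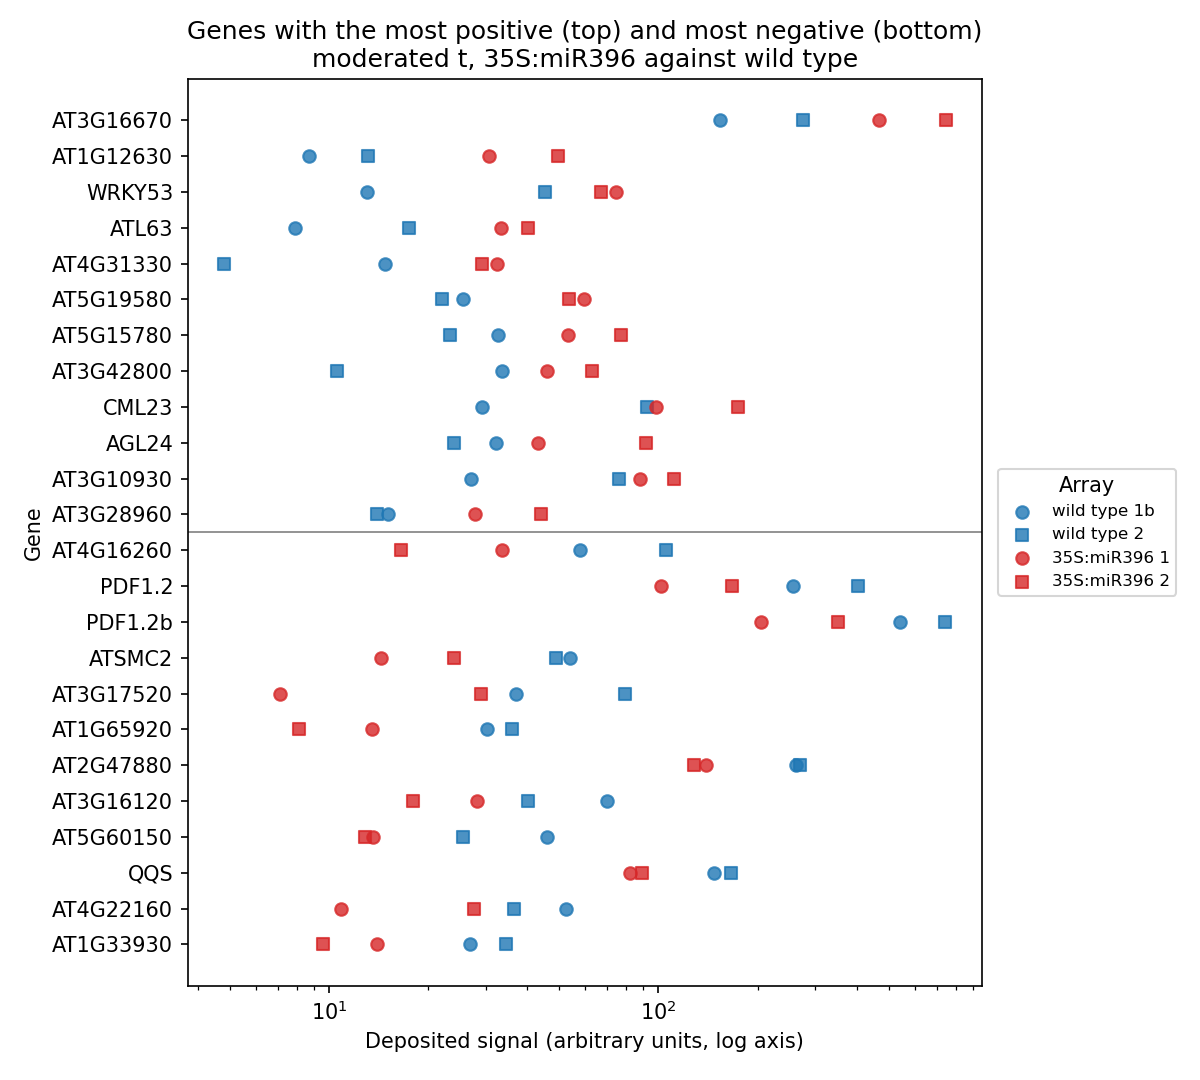
Deposited signal (arbitrary units, log axis) of the 12 genes with the highest and the 12 with the lowest moderated t among genes that separate the genotypes, 1 point per array. For PDF1.2 the wild-type arrays read 257 and 405 and the 35S:miR396 arrays 102 and 167.

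The direct targets of miR396 could not be read. The GROWTH-REGULATING FACTOR (GRF) genes, transcription factors of leaf cell proliferation, are the known targets of this microRNA, and the annotation used here paired 0 of the 7 GRF genes with a miR396 site and 0 of the 5 other GRF genes and their GIF partners with a probe set of its own. The overexpression named in the labels was therefore not checked through these transcripts. Of 4 other reported or predicted targets, 1 was measured: the gene of a rhodanese-like protein, AT2G40760, was at 206 ± 1.63 (SD, n = 2) in wild type and 190 ± 10.8 in 35S:miR396, a log2 fold change of -0.12 that did not pass, also when adjusted over the list alone.

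Genes of mitosis and cytokinesis fell as a list in 35S:miR396 in the camera test with a preset correlation (adjusted p = 1.2e-04). The call is lost with an estimated correlation (adjusted p = 0.855) and in the fry test (adjusted p = 0.986). The loss in camera does not show that members varying together made the call, as its degrees of freedom also drop to 2. The list of G2/M and cytokinesis genes had 7 tested members of 40. Its median log2 fold change was -0.39, with 6 of 7 members below 0. On the deposited signals 5 of 7 were lower on both 35S:miR396 arrays than on both wild-type arrays, but 35S:miR396 1 was the dimmest array. After centring, SCL28 and 3xHMG-box2, among these 5, were not lower in number 1 (log2 ratios 0.12 and 0.03). The kinesin PAKRP1L, which acts at the phragmoplast during cytokinesis, was at 42.2 and 60.5 in wild type and 34.9 and 31.5 in 35S:miR396. The DNA-binding protein 3xHMG-box1, which sits on mitotic chromosomes, was at 51.1 and 66.0 against 37.2 and 38.4. The aurora kinase AUR1 was at 118 and 150 against 91.2 and 112, and SCL28, a transcription factor of G2/M progression, was at 21.0 and 36.4 against 19.2 and 11.7. AUR3 had a log2 fold change of 0.01. None of the 7 members passed alone, whether over all probe sets or adjusted over the list alone. Between arrays of number 1, centred on their medians, the median was 0.00 with 3 of 7 members below 0, and between those of number 2 it was -0.71 with 6 of 7 below 0. Without wild type 2 the median was -0.22 (adjusted p = 0.460) and without 35S:miR396 2 it was -0.53 (adjusted p = 0.199). In that order, the median over all probe sets in these fits was -0.07 and -0.22. The split of wild type 2 and 35S:miR396 1 against the other arrays gave a camera p as small as that of the genotypes. That split sets the genotype difference in number 1 against that in number 2, so a shift in 1 number alone moves both splits.

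Other growth-related lists did not pass the camera test in the comparison without a term for the replicate number. The 5 tested core histone genes, all of the H2B class, had a median log2 fold change of -0.22 with 5 of 5 below 0 (adjusted p = 0.0657). HTB1 was at 287 and 305 in wild type and 189 and 279 in 35S:miR396, and HTB3, HTB4 and HTB11 had log2 fold changes of -0.26, -0.22 and -0.21. After quantile normalization the histone list fell, with a median of -0.16 (camera adjusted p = 0.00813, and 0.633 with an estimated correlation). That estimate was 0.0017, under the preset 0.01, so correlation does not account for this loss. On the deposited signals the histone median was -0.04 without 35S:miR396 1 and -0.45 without 35S:miR396 2. The median over all probe sets moved the same way, to 0.15 and -0.22, so this change is in part shared by all probe sets. The 7 tested expansins, proteins that loosen the cell wall, had a median of -0.33 with 6 of 7 below 0 (adjusted p = 0.0657), and without 35S:miR396 1 the median was 0.22. With the replicate number as a block their adjusted p in camera was 0.0112, and 0.762 with an estimated correlation. EXPB1 had the largest absolute moderated t of the expansins, at 30.8 and 50.7 against 6.60 and 37.1, followed in that ranking by EXPA9 (log2 fold change -0.43), EXPA16 (0.34) and EXPB3 (-0.33). Of the DNA replication genes 2 were tested: PROLIFERA, the MCM7 helicase subunit, had a log2 fold change of -0.24 and ICU2, a DNA polymerase subunit, one of 0.17. The only measured gene of the shoot meristem and leaf primordium list, CLV3, lay under the filter on low signals, and no CIN-type TCP gene had a probe set of its own in the annotation.

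Defence and flowering lists held too few members for a list test. Both measured members of the jasmonate and wound list, PDF1.2 and PDF1.2b, fell when adjusted over the list alone (2 of 2, largest adjusted p = 0.00323), and 0 of 2 passed over all probe sets. They encode near-identical defensins and PDF1.2b was read by a probe set of a type that can cross-hybridise, so the pair is not 2 independent readings. Of the salicylic acid list, WRKY53 was higher and passed when adjusted over the list alone (1 of 2, adjusted p = 0.0138), but not after quantile normalization (adjusted p = 0.128), and SAG101, a lipase-like immune regulator, had a log2 fold change of -0.25. AGL24 was the only tested flowering gene, so its limma p of 0.0168 is unadjusted, and it did not pass over all probe sets. The values adjusted over a list alone, and that of AGL24, take no account of the number of lists.

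Photosynthesis and stress lists did not pass the camera test in that comparison. The 6 tested nuclear photosynthesis genes, among them LHCB4.1 of the light-harvesting antenna at 13180 ± 84.0 (SD, n = 2) in wild type and 12641 ± 1225 in 35S:miR396, had a median log2 fold change of -0.04 (adjusted p = 0.688), which turned to 0.022 after quantile normalization. Its members PSBW, LHCB4.2 and PSAE1 had log2 fold changes of -0.15, -0.04 and -0.04. Cold and abscisic acid genes had a median of -0.11 (adjusted p = 0.575), early auxin response genes one of -0.05 (adjusted p = 0.987), and dark and sugar-starvation induced genes one of 0.14 (adjusted p = 0.325). In these last 3 lists the direction turned when single arrays were left out. COR15A, a cold-induced chloroplast protein, was at 434 and 378 on the arrays of number 1 and at 1783 and 2761 on those of number 2, while COR47 (4194 and 3278 against 3634 and 4349) and GH3.5 (309 and 156 against 102 and 164) overlapped between the numbers. LTI30, COR15B and COR47 had log2 fold changes between the genotypes of -1.03, -0.16 and -0.05, the auxin genes GH3.3, IAA29, GH3.5 and HAT2 of -0.50, 0.48, -0.15 and 0.06, and the starvation genes MCCB, IVD and MCCA of 0.20, 0.11 and 0.14. The flavonoid list had 2 tested members, UGT78D2 (-0.21) and DFR (-0.10), and the glucosinolate list 2, BCAT4 (-0.11) and UGT74B1 (0.10). Single members stood for the heat shock list (HSA32, log2 fold change 0.13), the evening clock list (GIGANTEA, 0.00), the root markers (PYK10, 0.09) and the type-A response regulators (ARR16, 0.08). No morning clock gene had a probe set of its own in the annotation.

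**Figure D2:**
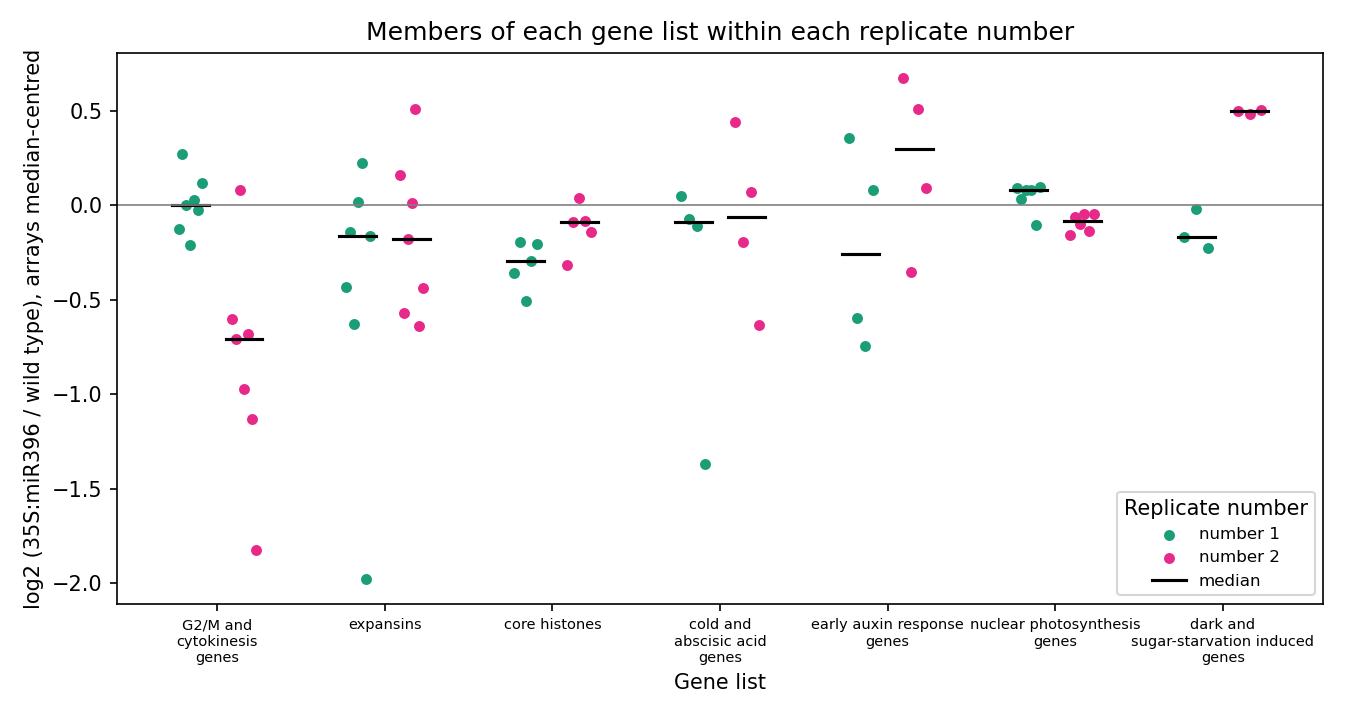
Log2 ratio of 35S:miR396 to wild type for each tested member of the 7 gene lists with 3 or more members, within replicate number 1 and within number 2, after each array was centred on its median. Points are genes and bars are medians, and the G2/M list lies at 0.00 in number 1 and at -0.71 in number 2.

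A count without a test gave few genes that separated the genotypes widely. In 35S:miR396, 3 probe sets were at least 2-fold higher than wild type in every one of the 4 pairs of arrays and 4 were at least 2-fold lower. AT1G12630 and AT5G19580, a glyoxal oxidase-related gene, were among the 3, and ATSMC2 and AT1G65920 among the 4, while the remaining 3 probe sets had no single gene in the annotation. The other splits of the 4 arrays gave 482 probe sets when the arrays of number 2 were set against those of number 1, and 7 when wild type 2 and 35S:miR396 1 were set against the rest. At 1.5-fold the counts were 67, 1386 and 95 for the genotype, the number and the crossed split, and without the filter on low signals they were 575, 1130 and 593 at 2-fold. With the lowest 60% left out the genotype count was 0, and with single arrays left out it was 87 to 233. Arrays of the same number also resembled each other most. Across the 15923 probe sets, the SD of log2 differences was 0.36 between the arrays of number 1 and 0.35 between those of number 2, against 0.58 between the wild-type arrays and 0.57 between the 35S:miR396 arrays. After each array was centred on its median, the log2 ratios of 35S:miR396 to wild type in number 1 and in number 2 had the same sign in 50.4% of probe sets.

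**Figure D3:**
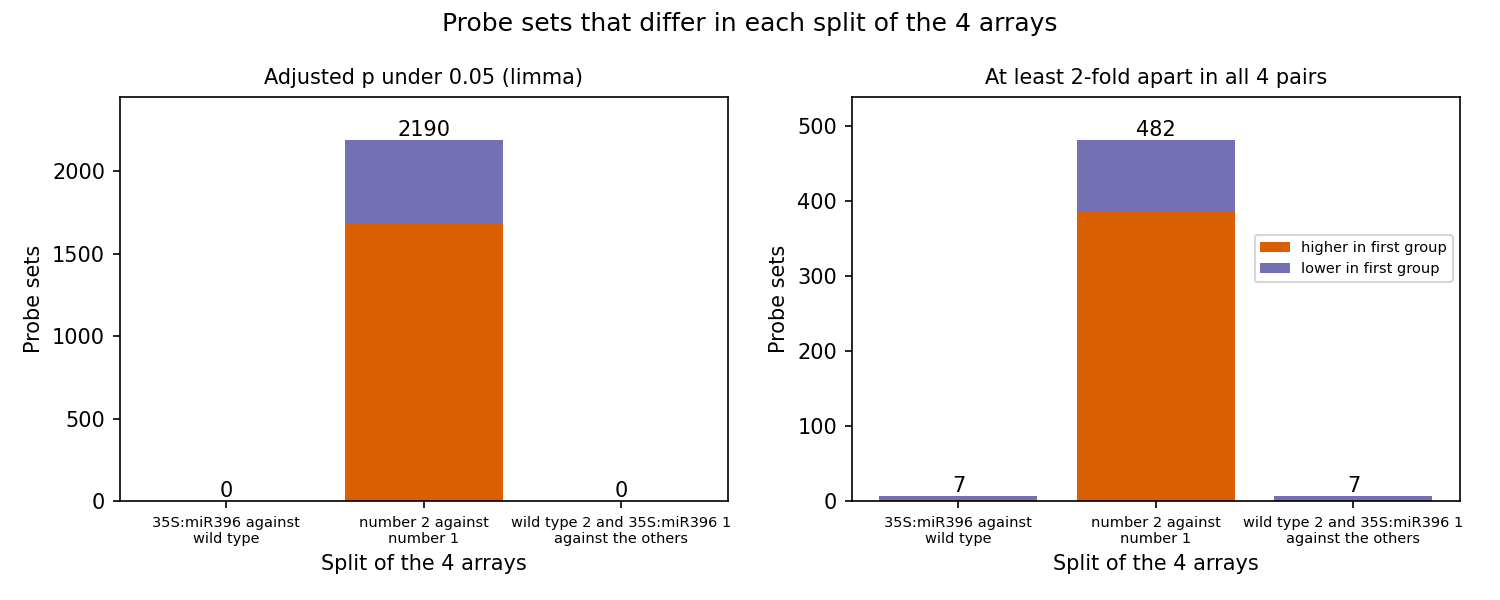
Number of probe sets that pass an adjusted p of 0.05 in limma (left) and that are at least 2-fold apart in all 4 pairs of arrays (right) for each of the 3 splits of the 4 arrays, stacked by direction. The split by genotype gives 0 and 7, the split by replicate number 2190 and 482, and the crossed split 0 and 7.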

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

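One Affymetrix control probe set for a bacterial transcript, the 3' probe set of the TrpnX control, was higher on both 35S:miR396 arrays (8.90 and 6.70) than on both wild-type arrays (0.3 and 3.0), by at least 2.23-fold in every pair. It lies outside the measurement of plant genes, and all 4 signals were below 15.8, the lowest mean signal kept for testing.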

How the results depend on the processing

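Alternatives chosen after the data were seen were the block combined with another scaling and the arrays left out for the count of probe sets 2-fold apart. No probe set passed under quantile normalization, centring, no filter, a pseudocount, no trend, robust fitting or an adjusted p of 0.1. With the lowest 60% left out 3 passed (AT3G16670 higher, AT3G02480 and an unnamed probe set lower), and with arrays left out in turn 0 to 2 did (AT3G02480 in each count of 2, with an unnamed probe set). With 60% left out, the calls as lower rested on 35S:miR396 1. At an unadjusted p under 0.05 there were 85, and 69 with at least 2-fold. Probe sets 2-fold apart in every pair numbered 67 at 1.5-fold, 0 at 3-fold, 575 without a filter, 0 with the lowest 60% left out, 4 after quantile normalization, 3 with a pseudocount, and 87 to 233 with arrays left out, where 2 pairs remain instead of 4. Of 7 lists, 1 passed as reported, 2 after quantile normalization, centring or the filter on the lowest 60% (there the histone and cold lists), 2 to 5 with arrays left out, and 0 with an estimated correlation or fry.

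The G2/M list kept its direction under all alternatives run. Its median was -0.39 with an estimated correlation (adjusted p = 0.855) and in fry (0.986), -0.36 with the lowest 60% left out (adjusted p = 0.0859, 1 member tested), and -0.65 to -0.22 with arrays left out. The medians of other lists turned with arrays left out: cold and abscisic acid -1.19 to 0.84, dark and sugar starvation -0.74 to 1.15, early auxin -0.86 to 0.67, expansins -0.82 to 0.22, photosynthesis -0.13 to 0.047. The lone array was then assumed to vary like the other group. The median over all probe sets moved as well. It was 0.15, -0.22, -0.02 and -0.07 without 35S:miR396 1, 35S:miR396 2, wild type 1b and wild type 2 in turn. The photosynthesis median was also 0.022 after quantile normalization, with or without the block. For the list medians the cause was not tested. The 24 named genes were picked for arrays that do not overlap, so their direction cannot turn when an array is left out, but the log2 fold changes of 7 of the 12 higher and 2 of the 12 lower then shrank by over 1.5 times. Of 316 values of these genes under alternatives, 6 passed the threshold. The GRF targets gave no value under any alternative.

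The labels do not say that replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at 0.627 across probe sets, over 2 pairs. With the replicate number as a block, 5 probe sets passed: AT3G16670 higher, AT4G16260 lower, and LEA4-5, AT3G02480 and an unnamed one lower through 35S:miR396 1. With the block, quantile normalization gave 0 and centring 3 (AT3G16670 higher, PDF1.2 and PDF1.2b lower). In that order, 2, 4 and 3 lists passed: the G2/M list in each, the expansins in each (adjusted p = 0.0112, 0.0210 and 0.0263), the histones with the block and quantile normalization (0.00472) or centring (0.00493), and the dark and sugar-starvation list with the block and quantile normalization (0.0423). With an estimated correlation no list passed in these 3 fits, and the adjusted p of these lists was 0.76, 0.63 and 0.60. Camera then had 1 degree of freedom. MAS5 signals near background limit what the dim genes can show: 4 of the 12 higher and 4 of the 12 lower named genes had a mean under 50 in both genotypes.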

Other observations

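The tests between replicate numbers and those on brightness, RNA degradation and wild type 2 were chosen only after the pattern was seen, while those on the second mitosis list and on the splits for the G2/M list were set before their results.

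The arrays of number 2 differed from those of number 1 in the lists of cold, starvation, auxin and expansin genes, in camera tests with a preset correlation over both genotypes together. These list calls were lost with an estimated correlation, where camera has 1 degree of freedom. With genotype in the limma model and quantile normalization, 2929 probe sets passed, 1545 higher and 1384 lower in number 2, and on the deposited signals the same model called 888, of which 690 were higher and 198 lower. Log2 fold changes and list tests between the numbers are given after quantile normalization, and signals as deposited. Of the cold and abscisic acid list 3 of 4 members rose, with a list median log2 fold change of 1.99 (camera adjusted p = 1.6e-04, and 0.502 with an estimated correlation). The dehydrin LTI30 was at 277 and 90.4 on the arrays of number 1 and at 1643 and 1206 on those of number 2, a log2 fold change of 2.97, and COR15B had one of 1.69. The expansin EXPA8 rose from 230 and 176 to 1193 and 917, and the expansin list had a median of 0.31 (adjusted p = 0.0427, and 0.502 with an estimated correlation). BHLH101, a transcription factor of the iron deficiency response, rose from low signals of 16.1 and 5.20 to 118 and 100. AT2G15020 was at 8.2 and 2.1, near background, on the arrays of number 1 and at 105 and 117 on those of number 2.

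The dark and sugar-starvation list and the early auxin response list fell in number 2. Of the starvation genes 3 of 3 passed, against 2 of 3 on the deposited signals, with a median of -1.57 (adjusted p = 3.5e-04, and 0.502 with an estimated correlation). MCCA and MCCB, the subunits of methylcrotonyl-CoA carboxylase, had log2 fold changes of -2.08 and -1.57, and IVD, the preceding enzyme of leucine breakdown, one of -0.74, although its signals of 1302 and 1293 in 35S:miR396 were alike. Of the auxin genes 4 of 4 passed, against 2 of 4 on the deposited signals, with a median of -1.45 (adjusted p = 1.6e-04, and 0.502 with an estimated correlation), and IAA29, GH3.3, HAT2 and GH3.5 had log2 fold changes of -2.32, -1.71, -1.19 and -0.94. The fall of GH3.5 was not seen in 35S:miR396, with signals of 156 and 164. GAT1_2.1, which encodes a class I glutamine amidotransferase, went from 938 and 596 to 69.5 and 224. XTH33, a cell wall xyloglucan enzyme, went from 140 and 173 to 32.3 and 44.8. The evening clock gene GIGANTEA did not pass (log2 fold change 0.33).

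The difference between replicate numbers was weighed against the arrays and the RNA. A difference in brightness is argued against by the 2958 probe sets that passed after quantile normalization, where 2190 passed on the deposited signals, both without genotype in the model. RNA degradation stays open: the ratios of 3' to 5' control probe sets were on average lower in number 2 for 5 of 6 pairs, with log2 differences from -0.27 to 0.12 and a median of -0.10. For ubiquitin in the first design the arrays overlapped between the numbers (log2 difference -0.02). A difference in the light, sugar or cold state of the plants may account for the pattern, as a hypothesis, but it was drawn from the shifts of the dark and cold lists themselves, so the larger of their adjusted p values (3.5e-04, and 0.502 with an estimated correlation) is no test of it. It stays open, as does a hybridisation batch that follows the number, which was not tested.

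The lower G2/M list in 35S:miR396 may reflect lower expression of mitosis genes, as would follow from fewer dividing cells under miR396 overexpression, a hypothesis that stays open. A second list of 22 tested mitosis genes without members of the first had a median log2 fold change of -0.32 with 16 of 22 below 0 (camera p = 2.9e-05, and 0.200 with an estimated correlation). However, the crossed split of the arrays also gave it a camera p of 3.9e-04 (0.0234 after quantile normalization). The crossed split sets the genotype difference in number 1 against that in number 2. A shift in 1 number alone moves both splits, so the crossed split is no separate comparison. Array brightness was not decided by the camera test. Camera sets the list against all other probe sets, so a shift shared by all of them drops out before any normalization. After quantile normalization the list median was -0.36, with a camera adjusted p of 6.2e-04 at the preset correlation (0.666 with an estimated correlation). A high level on wild type 2 alone stays open. Within number 1, which leaves out that array and 35S:miR396 2, the median of the G2/M list was 3.6e-04 with members on both sides of 0. That of the second list was -0.15 with 15 of 22 below 0. As both arrays drop out, this comparison cannot tell a high wild type 2 from a low 35S:miR396 2. On the deposited signals the median of the second list was -0.19 without wild type 2 and -0.34 without 35S:miR396 2 (16 and 21 of 22 below 0). In that order, the median over all probe sets was -0.07 and -0.22. Camera gave a p as small in 2 of the 3 splits of the 4 arrays, 1.8e-05 for the genotypes and 6.6e-06 for wild type 2 and 35S:miR396 1 against the rest, and 3 splits are too few for a share under 0.05.

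A further list of 5 DNA replication genes had a median log2 fold change of 0.14 in 35S:miR396 and did not pass the camera test.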
